A study of Mus musculus with 30 samples.

How the data were processed

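The series held 30 mouse (C57BL/6) ChIP-seq samples, of which 21 had peak lists that were analysed: 5 for H3K4me3, 6 for H3K27ac and 5 for H3K27me3 in ER-Hoxa9-Lys-GFP cells, 3 for V5 and 2 for AM in the V5-Hoxa9-AM line and its ER counterpart, V5-ER-Hoxa9-AM. The other 9, which were 7 inputs and the V5 and AM ChIPs after 96 h without E2, were not analysed here. Groups were taken from the sample titles and treatment labels. Both AM samples with lists carry V5 as their antibody label and were grouped by title. Per the labels' protocols, cells were grown with stem cell factor medium, E2 was removed by washing, and 500 ug of chromatin was used for histone marks and 30 ug for V5 and AM.

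The deposited files were peak lists with the chromosome, start and end coordinates of each peak and no score, height or p-value, so their unit was taken as other: coordinates. Per the submitters' processing notes the tools were Bowtie2 2.0, BWA and MACS2 2.0 with the builds mm9 and mm10; which tool and build belonged to which file, the read depth, the calling threshold and the use of inputs were not given in the sources used here. The build of each list was inferred from its coordinates and the GRCm38.p6 gene table. H3K4me3 peaks of the E2 list fell within 1 kb of a gene end in 62.3% of cases and in 7.28% after a shift of 100 kb, and those lists, with V5 and AM, were treated as mm10 (V5-Hoxa9-AM V5 10.8% and 4.90%; the short V5-ER-Hoxa9-AM lists alone gave no contrast, but 76.1% of the E2 V5 sites, 79.5% of the E2 AM sites and 97.2% of the 72 h V5 sites had the coordinates of a V5-Hoxa9-AM V5 site). H3K27ac and H3K27me3 lists gave 8.27% and 6.48% in E2 against 7.11% and 6.66% after the shift, and reached 197003115 on chromosome 1 where the last gene ends at 195176880, and were treated as mm9. Lists on different builds were never compared, so no gene is named for H3K27ac or H3K27me3 and V5 sites were compared with H3K4me3 only.

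Peaks on chromosomes 1 to 19 and X were used; chromosome Y was not analysed here. A peak of the E2 list was called lost if no peak of the 120 h list overlapped it by 1 bp, a peak of the 120 h list gained if no E2 peak overlapped it, and all others common (counted in the E2 list unless stated). Each restored list was scored by the share of lost, gained and common peaks it overlapped. Shares carry 95% Clopper-Pearson intervals and differences Newcombe intervals; both cover peak-counting error only, and neighbouring peaks are not independent. Differences were also counted per chromosome over 20 chromosomes. Random placement used 100 shuffles of the peaks within their chromosomes.

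The gene table held 21631 protein-coding genes on chromosomes 1 to 19 and X and gave no strand, so a gene was called marked if an H3K4me3 peak overlapped 1 kb on either side of either gene end, and the covered length was summed over those windows. Promoters inside a gene are missed by this measure. The log2 ratio of covered length used a pseudocount of 50 bp. All 15 gene lists were fixed before the data were examined (367 entries, 1 of them, Mx1, unmatched). The number of list genes gaining or losing the mark was set among 10000 random lists, drawn from the 10323 genes marked in E2 or at 120 h and matched on quintile of mean covered length. Each random list had as many genes as the fixed list had marked in E2 or at 120 h. This was 27 of 34 for neutrophil maturation and 1 of 40 for developmental Polycomb targets. Genes with a V5 or AM site within 10 kb were counted against lists matched on gene length. Percentiles rank values of these single libraries among random lists and give no p-value.

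Genes were named by a rule: up to 4 genes per list, the 12 genes per direction with the widest peak among genes marked in only E2 or only 120 h, the 12 widest V5-Hoxa9-AM V5 sites and the 12 widest sites in all V5 lists with their nearest gene, and Hoxa9, Meis1, Lyz2, Mpo, Elane, Cd34, Kit, Flt3, Myb, Spi1, Cebpa, Cebpe, Itgam, Ltf and Gapdh. Other named genes were chosen after their values were seen: Ngp, S100a8, S100a9, Mcemp1, Cd14, Ccr2, Ctsg, Prtn3, Nfe2, Cdk6 and Muc13 among the V5 sites, Stard10 and Srf among the lost genes near a V5 site, and the histone and Gimap families.

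Several steps departed from the plan. The rule was to rank by the authors' score; as the lists hold none, peak width was used throughout. For the same reason the alternatives based on score were replaced by peaks above the median width and by lists reduced to their widest peaks at equal length (17497 for H3K4me3, 24930 for H3K27ac, 3845 for H3K27me3, 258 for V5 and AM; the shorter 56 h H3K27ac list was kept whole), both chosen after seeing the data, as was marking a gene by any peak within it or 1 kb around it. Transcription start sites were replaced by gene ends. Promoter states over all 3 marks were replaced by overlaps of H3K27ac and H3K27me3, and sequence motifs were not analysed here, as no genome sequence was used. The other alternatives were 50% of a peak covered, peaks within 1 kb merged, and a window of 2.5 kb. For Cebpe, Mpo and the other genes tabulated with coordinates these are the GRCm38 gene spans.

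Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Overlaps were checked against bedtools 2.31.1. The overlap step was tested on simulated data made from each mark's E2 list: all 200 peaks made lost and all 200 made gained were found for H3K4me3, for H3K27ac and for H3K27me3. In these data near peaks were merged first, starts moved little and added peaks lay apart from others. The test thus checked the code only, not split, shifted or weak peaks. For the H3K4me3 comparison of E2 with 120 h over 10323 genes, lists of 25 genes with no added effect passed the upper percentile limit in 5 of 200 cases, and lists made to gain in 50% of genes against a base of 12% passed it in 49 of 50. The base was the same at every covered length, whereas lists matched to neutrophil maturation gained 13.1 of 27 genes on average. The simulation thus did not test the matching on covered length.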

Results

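Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to follow mouse cells whose growth state depends on estradiol (E2). The cells carry HOXA9, a homeodomain transcription factor of blood progenitors and of acute myeloid leukaemia, fused to the hormone-binding domain of the estrogen receptor (ER-HOXA9). The fusion protein is active while E2 is present. The series asked how chromatin differs before and after commitment to myeloid differentiation. ER-Hoxa9-Lys-GFP cells were kept in E2, deprived of E2 for 120 h, or deprived for 24, 40, 56 or 72 h and then returned to E2 for 96, 80, 64 or 48 h. Lists of peaks were analysed for H3K4me3, a mark of active promoters, for H3K27ac, a mark of active promoters and enhancers, and for H3K27me3, the mark placed by Polycomb repressive complex 2. The 56 h condition had a list for H3K27ac only. In cells with V5-Hoxa9-AM and in cells with its ER fusion, V5-ER-Hoxa9-AM, sites of the tagged proteins were mapped by ChIPs titled V5 and AM. Both AM samples with lists carry V5 as their antibody label. Each condition had 1 library per target, so no difference below has a replicate check, no p-value is given, and the 95% intervals (Clopper-Pearson for shares, Newcombe for differences) cover peak-counting error only.

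H3K4me3 peaks numbered 17497 in E2, 22871 at 24 h, 21329 at 40 h, 21790 at 72 h and 23835 at 120 h. H3K27ac peaks numbered 27876 in E2, 36845 at 24 h, 28791 at 40 h, 6356 at 56 h, 24930 at 72 h and 48710 at 120 h. For H3K27me3 the numbers were 4354, 5125, 3845, 5166 and 6927 in E2 and at 24, 40, 72 and 120 h. The V5 list of V5-Hoxa9-AM cells held 17006 peaks and its AM list 6773. In V5-ER-Hoxa9-AM cells the V5 list held 1417 peaks in E2 and 387 after 72 h without E2 and 48 h of restored E2, and the AM list in E2 held 258. Read depth was not given in the sources used here. The times 24, 40, 56 and 72 h below always mean the length of withdrawal before E2 was restored, whereas 120 h means withdrawal without restoration.

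The first comparison asked which genes carried H3K4me3 in E2 and after 120 h without E2. Of the 15 gene lists fixed beforehand, genes of neutrophil maturation had the highest percentile of gains: 3 of 34 had a peak within 1 kb of a gene end in E2 and 27 of 34 at 120 h. All 24 genes that differed gained the mark and 0 lost it, where lists of other genes matched on H3K4me3 coverage gained 13.1 on average (percentile 100 of 10000 matched lists). They included Cebpe, a transcription factor of late granulocyte maturation, Lcn2, Ltf and Ngp, which encode proteins of secondary granules, S100a8 and S100a9, the calprotectin subunits, and Csf3r, the receptor for granulocyte colony-stimulating factor. Peaks covered 3327 bp around the ends of Cebpe at 120 h and 0 bp in E2. The covered length at 120 h was 1702 bp at Lcn2, 1760 bp at S100a8, 1796 bp at S100a9, 1479 bp at Hp and 587 bp at Ltf, and none of these genes had a peak there in E2. Csf3r had H3K4me3 elsewhere in the gene in E2.

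Monocyte and macrophage genes went from 6 to 22 marked genes of 30, with 17 gained against 9.96 in matched lists (percentile 99.98) and 1 lost. Gained members included Csf1r, the receptor for macrophage colony-stimulating factor (733 bp at 120 h), Mpeg1, which encodes the pore-forming protein perforin-2 (2247 bp), Cd14, a co-receptor for lipopolysaccharide (1371 bp), and the transcription factor gene Klf4 (890 bp). F13a1, which encodes a subunit of coagulation factor XIII, also gained a peak but with 104 bp at 120 h, less than the 494, 237 and 263 bp at 24, 40 and 72 h, and it had H3K4me3 elsewhere in the gene in E2. The lost member was Ccr2, the receptor that directs monocytes to inflamed tissue, with 285 bp in E2. Surface and adhesion genes of mature myeloid cells went from 10 to 20 marked genes of 25, with 10 gained against 5.24 in matched lists (percentile 99.8), among them Itgam (CD11b, 1202 bp), the signalling adaptor gene Tyrobp (3138 bp), Ccr1 (949 bp) and Pilra (996 bp). Itgam was also a member of the neutrophil list. Interferon and inflammation genes went from 12 to 20 marked genes of 21, with 8 gained against 4.22 (percentile 99.5), including Nlrp3, the inflammasome sensor (1155 bp), Oas2 (1149 bp), Socs3 (717 bp, with H3K4me3 elsewhere in the gene in E2) and Ccl6 (583 bp). With only the peaks above the median width of each list, the percentile of the monocyte and macrophage list was 97.2.

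Primary granule genes did not move together. Mpo, which encodes myeloperoxidase, had 1112 bp of peaks around its ends in E2 and 0 bp at 120 h, and over the whole gene and 1 kb on either side its covered length was 5894 bp in E2 and 1270 bp at 120 h. Ctsg (cathepsin G) had 3531 bp in E2 and 923 bp at 120 h, whereas Prtn3 (proteinase 3) had 1399 bp and 1361 bp. Igsf6, Ms4a3 and Fcnb gained the mark, with 1843, 948 and 605 bp at 120 h. Of the 12 genes, 9 were marked in E2 or at 120 h and set the size of the matched lists. The 3 gains lay at percentile 98.7 of matched lists. With peaks above the median width the gains were counted anew, without Fcnb, and lay at percentile 76.2.

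Stem and progenitor genes showed the opposite balance to the maturation lists. Of 41 genes, 29 were marked in E2 and 26 at 120 h; 0 gained the mark against 3.21 in matched lists (percentile 0.54), and 3 lost it against 0.205 (percentile 99.96). The lost genes were Muc13, a transmembrane mucin, Mycn, a MYC-family transcription factor, and Dntt, the terminal transferase of antigen receptor rearrangement, with 905, 431 and 271 bp in E2. At the gene ends, Flt3, a cytokine receptor of early progenitors, covered 1516 bp in E2 and 652 bp at 120 h, Cd34, a surface marker of progenitors, 898 and 798 bp, Kit, the receptor for stem cell factor, 1477 and 1524 bp, Myb, a transcription factor of proliferating progenitors, 1182 and 1515 bp, and Meis1, a HOXA9 cofactor gene, 964 and 1878 bp. Over the whole gene and 1 kb on either side the lengths were 2060 and 1514 bp for Flt3, 4628 and 1053 bp for Cd34, 4179 and 2365 bp for Kit, 5971 and 4428 bp for Myb, and 2923 and 3077 bp for Meis1. The direction for Kit and Myb thus depended on the measure. The median log2 ratio of covered length, 120 h over E2, was 0.40 for the list and 0.60 over all 10323 genes with a peak in either list, and the mean of the list lay at percentile 0.02 of matched lists. Gains and losses were counted anew in each other setting. The percentile of the gains was then 5.41 with a window of 2.5 kb and 7.25 with peaks above the median width. With those wider peaks 2 genes of the list lost the mark, at percentile 90.4.

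Myeloid transcription factor genes were mostly marked in both lists: 23 of 30 in E2 and 28 at 120 h. The 5 gains lay at percentile 92.4, while the mean log2 ratio of covered length lay at percentile 100. Cebpe, Irf5, Klf4, Spi1 and Nfe2 gained a peak at a gene end, and Nfe2 is named here because it completes the 5, not by the rule for named genes. Spi1, which encodes PU.1, already had 2339 bp of peaks within the gene and 1 kb around it in E2, and 5463 bp at 120 h. Cebpa, a transcription factor gene required for granulocyte differentiation, had 2475 bp at its ends in E2 and 2682 bp at 120 h. Klf4 and Cebpe each stood in 2 lists.

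Lists for other cell types and for general functions differed at few genes. All 20 cell cycle genes were marked in every one of the 5 lists. Housekeeping genes went from 17 to 19 of 20; the 2 gains, Actb and Hprt, had H3K4me3 elsewhere in the gene in E2. Chromatin modifier genes went from 18 to 19 of 22, with a gain at the demethylase gene Kdm6b, which had H3K4me3 elsewhere in the gene in E2. Erythroid and megakaryocyte genes went from 2 to 3 of 18 (Epor gained), lymphoid genes from 3 to 5 of 20 (Cd79a, Tcf7 and Cd3d gained, Rag2 lost), genes of mast cells, eosinophils, basophils and dendritic cells from 3 to 4 of 18 (Flt3l gained), fibroblast and epithelial genes from 1 to 2 of 15 (Pdgfrb gained) and developmental Polycomb target genes from 0 to 1 of 40 (Hoxd13 gained). The gained percentiles of these 8 lists ran from 9.97 for chromatin modifiers to 93.3 for housekeeping genes. Some rest on few genes marked in E2 or at 120 h, with 1 developmental Polycomb target and 2 fibroblast and epithelial genes. The erythroid and megakaryocyte list had 3, the mast cell, eosinophil, basophil and dendritic list 4 and the lymphoid list 6. Hoxa9 itself had 154 bp in E2 and 116 bp at 120 h, and Gapdh 910 bp and 1312 bp. No peak was listed at Lyz2 or Elane in the 5 lists used here.

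**Figure D1:**
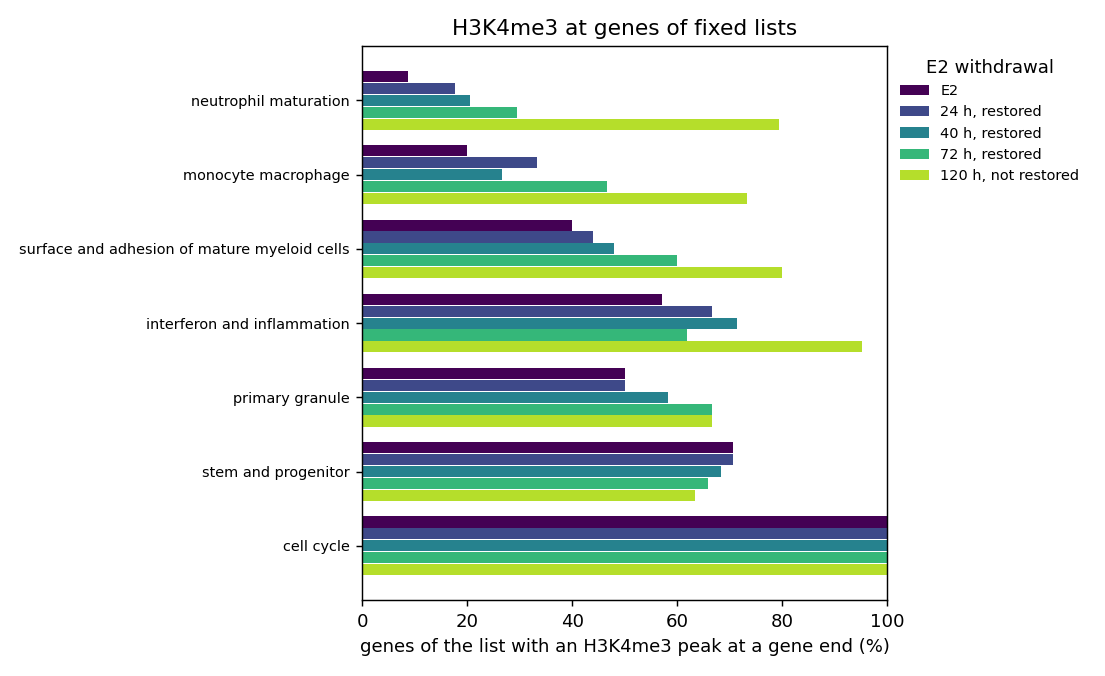
Horizontal bars give the percentage of genes of a fixed list with an H3K4me3 peak within 1 kb of a gene end, for each list of genes and each of 5 conditions (1 library each). Neutrophil maturation genes were marked at 3 of 34 in E2, 10 of 34 at 72 h and 27 of 34 at 120 h, whereas all 20 cell cycle genes were marked throughout.

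Over all 21631 genes considered, 9045 were marked in E2 and 10243 at 120 h: 8965 in both, 80 in E2 only and 1278 at 120 h only. These counts changed with the peaks kept: peaks above the median width gave 279 genes in E2 only and 2425 at 120 h only, and lists of equal length 151 and 1019. Among genes marked at an end only at 120 h, those with the widest peak were Cebpe, Ceacam1, a cell adhesion receptor, Stfa1 and Cstdc5, members of the stefin and cystatin family of protease inhibitors, Arrb2 (beta-arrestin 2), Irf5, an interferon regulatory factor, Mafg, a small MAF factor, and Klf13, Pde3b, Anp32b, Ap5b1 and Macir. The peak at Ceacam1 (mm10 chromosome 7, gene 25461702 to 25477647) was 3874 bp wide and that at Cebpe (chromosome 14, 54710363 to 54712174) was 2912 bp wide. In E2, Ap5b1, Macir, Pde3b, Mafg, Klf13, Anp32b and Irf5 had H3K4me3 elsewhere in the gene.

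Among genes marked at an end only in E2, the one with the widest peak was Mpo (chromosome 11, 87793784 to 87804412, 4529 bp), although narrower peaks of the 120 h list lay inside that peak. The 11 after it included Rag2, a subunit of the V(D)J recombinase, Igll1, a part of the pre-B cell receptor, Gimap6, an immune-associated GTPase, Tespa1, which acts in thymocyte development, and the receptor genes Cd72 and Cd244a. Rag2 (chromosome 2, 101624712 to 101632528) covered 1114 bp in E2, Tespa1 970 bp, Igll1 909 bp, Gimap6 801 bp, Cd244a 482 bp and Cd72 441 bp, each with 0 bp at 120 h. The rest were Gpr12, Smim41, Muc13, Rbm48 and Bcl2l15. Mpo, Gpr12, Smim41, Cd244a, Rbm48 and Bcl2l15 kept a peak elsewhere in the gene at 120 h.

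By peaks rather than genes, 1323 H3K4me3 peaks of the E2 list were lost at 120 h (7.56%, 7.17 to 7.96) and 9820 peaks of the 120 h list were gained (41.2%, 40.6 to 41.8). Common peaks lay within 1 kb of a gene end in 72.7% of cases, gained peaks in 36.7% and lost peaks in 26.7%. Gained peaks were narrow, with a median width of 316 bp against 827 bp for common peaks of the 120 h list, and common places covered 1.34 times more length at 120 h than in E2. The lists therefore differed in how much was called as well as where.

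**Figure D2:**
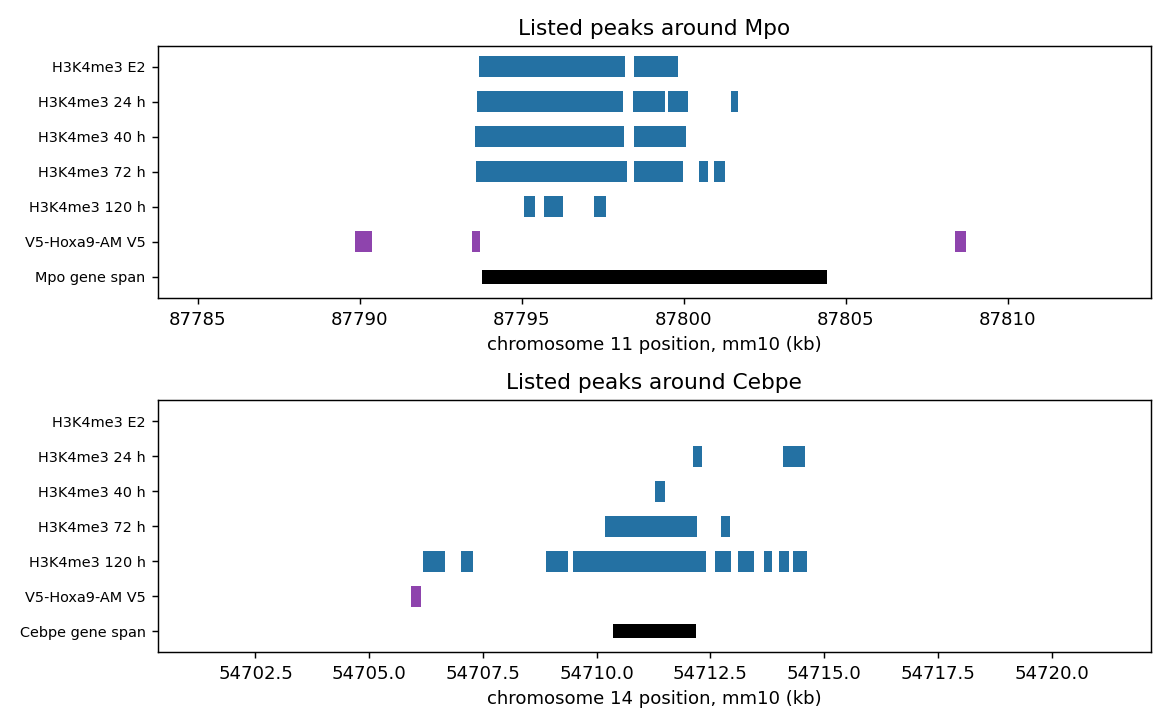
H3K4me3 peaks of the 5 conditions and V5 peaks of V5-Hoxa9-AM cells are drawn to scale along mm10 (kb) around Mpo and Cebpe, with the gene span in black. Around the ends of Cebpe the peaks covered 0 bp in E2, 2234 bp at 72 h and 3327 bp at 120 h, while within Mpo and 1 kb around it they covered 5894 bp in E2 and 1270 bp at 120 h.

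The second comparison asked, for each length of withdrawal, whether H3K4me3 after restored E2 was closer to the E2 list or to the 120 h list. For every mark, a longer withdrawal came with less time back in E2 (96 h at 24 h, 48 h at 72 h). Their effects cannot be told apart. After 24 or 40 h without E2, the H3K4me3 of the E2 state was largely present: 85.0% of the 80 lost genes were marked at 24 h and 88.75% at 40 h, but 46.25% (35.0 to 57.8) at 72 h. The 80 genes are those of the full lists, and their number changed with the peaks kept, as given above. Of the 1278 gained genes, 51.1% were marked at 24 h, 49.7% at 40 h and 66.6% (63.9 to 69.2) at 72 h. Neutrophil maturation genes were marked at 6, 7 and 10 of 34 at 24, 40 and 72 h, against 27 at 120 h. Monocyte and macrophage genes were marked at 10, 8 and 14 of 30, against 22, and surface genes at 11, 12 and 15 of 25, against 20. With peaks above the median width, 6 neutrophil maturation genes and 7 monocyte and macrophage genes were marked at 72 h. Interferon and inflammation genes were marked at 14, 15 and 13 of 21, against 20.

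Single genes followed different courses. Cebpe had 200 bp at 24 h, 224 bp at 40 h and 2234 bp at 72 h, when E2 had been back for 48 h. Igsf6 had 358 bp at 40 h and 1618 bp at 72 h, Ms4a3 1157 bp at 72 h only among the restored lists, Mpeg1 1427 bp at 72 h and Tyrobp 1567 bp. In contrast, Lcn2, Ltf, S100a8, S100a9, Ngp and Mcemp1 had no peak at a gene end in any restored list. Itgam had 286 bp at 72 h against 1202 bp at 120 h. Of the lost genes, Muc13, Igll1 and Cd72 had 0 bp at 72 h after 1005, 1098 and 270 bp at 40 h, and Rag2 had 397 bp after 1343 bp. Others stayed marked at 72 h, as did 37 of the 80 lost genes: Mpo had 1188 bp at its ends, Tespa1 870 bp, Gimap6 704 bp, Smim41 652 bp and Cd244a 377 bp. Flt3 had 1542, 1451 and 1233 bp at its ends at 24, 40 and 72 h, and Cd34 5030, 5690 and 3138 bp over the gene and 1 kb around it. S100a8, S100a9, Ngp and Mcemp1 were chosen as examples after their values were seen.

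Counted over peaks, 75.8% (73.4 to 78.1) of lost peaks were found at 24 h, 78.6% at 40 h and 55.2% (52.5 to 57.9) at 72 h, and 36.9%, 36.8% and 49.0% of gained peaks. Common peaks were found at 96.2%, 96.4% and 98.4%, too near 100% to show whether the lists differed in sensitivity. The difference, gained minus lost, was -38.9 points at 24 h, -41.8 at 40 h and -6.19 (-9.02 to -3.32) at 72 h, and gained exceeded lost on 0, 0 and 3 of 20 chromosomes. With peaks within 1 kb merged, the difference at 72 h was 5.26 points. Over all peaks of the restored lists, 85.4%, 88.1% and 91.4% at 24, 40 and 72 h were in the 120 h list. In the shorter E2 list 69.9%, 71.7% and 67.35% were found. In the other direction, 94.6%, 95.1% and 95.2% of E2 peaks were in the restored lists, and 72.3%, 72.6% and 78.0% of 120 h peaks. Which list was closer thus depended on the measure, and a difference of 0 points marks no midpoint.

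The same comparison for H3K27ac showed the wider turnover. Between E2 and 120 h, 10148 of 27876 peaks were lost (36.4%, 35.8 to 37.0) and 31960 of 48710 were gained (65.6%, 65.2 to 66.0). The widest gained peak lay on chromosome 7 of mm9, from 149576420 to 149584039, a stretch of 7620 bp that held no peak in E2 or at 24 h, 159 bp at 40 h and 2457 bp at 72 h. The next lay on chromosome 7 from 124625244 to 124629990 (4747 bp, with 832 bp at 72 h and 0 bp in E2, at 24 and at 40 h). Clusters of gained peaks filled single bins of 100 kb: 52 peaks lay between 117700001 and 117800000 of chromosome 2, where E2 and 24 h had 0 and 72 h had 6, and 52 between 116700001 and 116800000 of chromosome 10, where 72 h had 12.

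The widest lost H3K27ac peak lay on chromosome 8 from 35870382 to 35873418. Its 3037 bp were covered over 2631 bp at 24 h, 350 bp at 40 h and 0 bp at 56, 72 and 120 h. The next, on chromosome 8 from 124806608 to 124809597 (2990 bp), was covered over 2911, 2561, 508 and 246 bp at 24, 40, 56 and 72 h. The bin with most lost peaks, on chromosome 8 from 97500001 to 97600000, held 32 peaks in E2, 27 at 24 and at 40 h, 14 at 56 h, 12 at 72 h and 6 at 120 h. The next bin, on chromosome 7 from 73300001 to 73400000, held 37 in E2 and at 24 h, 32 at 40 h, 27 at 56 h, 21 at 72 h and 12 at 120 h. Genes are not named for H3K27ac and H3K27me3, whose lists were on mm9 while the gene table was on GRCm38.

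After restoration, 54.9% (53.9 to 55.8) of the lost H3K27ac peaks were found at 24 h, 40.3% (39.3 to 41.3) at 40 h and 14.5% (13.9 to 15.3) at 72 h. Gained peaks were found at 18.9%, 13.3% and 20.2%. The 24 h list was longer than the 72 h list (36845 against 24930 peaks) and found a similar share of gained peaks. Common peaks were found at 85.9%, 75.6% and 68.0%. Gained minus lost was -36.0 points at 24 h and -27.0 at 40 h, below 0 on all 20 chromosomes in both, and 5.61 (4.78 to 6.41) at 72 h, above 0 on 18 of 20. The sign at 72 h depended on the setting, at 1.69 when 50% of a peak had to be covered, 0.54 (-0.57 to 1.64) with lists of equal length and -1.23 with peaks above the median width. The 56 h list found 11.6% of common peaks, 7.59% of lost peaks and 5.64% of gained peaks, and its small size limits any reading of that time.

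**Figure D3:**
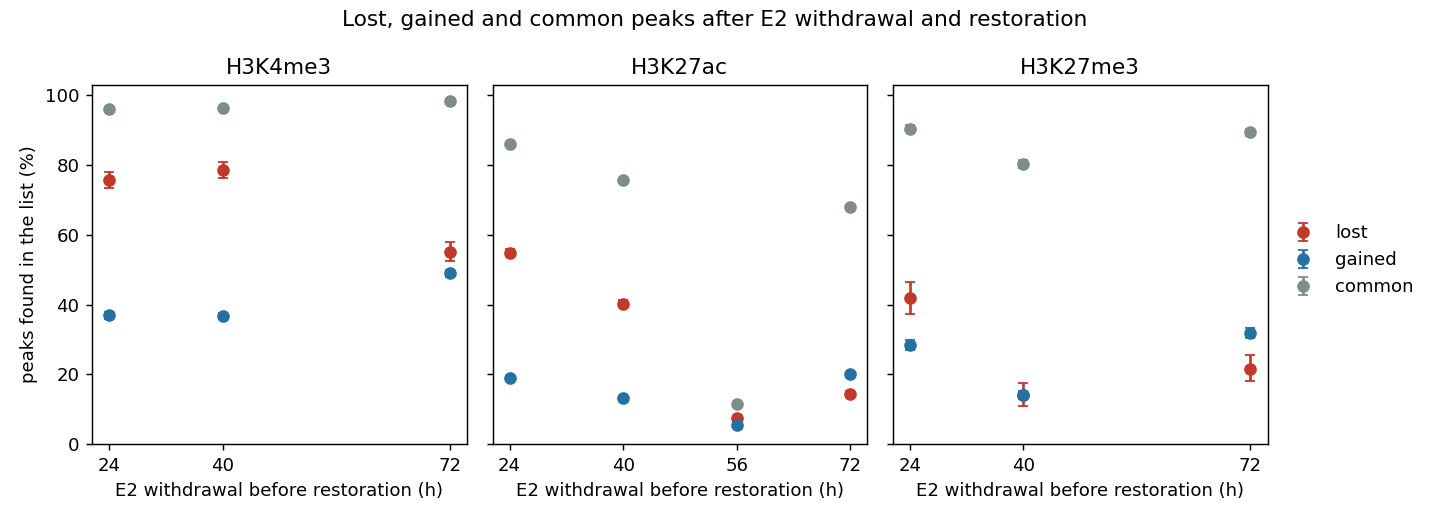
Points show the percentage of lost, gained and common peaks found in each restored list (y axis) against hours of E2 withdrawal before restoration (x axis) for the 3 marks, 1 library each, with 95% Clopper-Pearson intervals. For H3K27ac, 54.9% of lost peaks were found at 24 h and 14.5% at 72 h, whereas common peaks stood at 85.9% and 68.0%.

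For H3K27me3, 470 of 4354 peaks of the E2 list were lost at 120 h (10.8%, 9.89 to 11.8) and 3925 of 6927 were gained (56.7%, 55.5 to 57.8). The widest gained peaks were broad domains at the end of mm9 chromosome 7: one ran from 151633690 to 151654612 (20923 bp), with 0 bp in E2, at 24 h and at 40 h and 10464 bp at 72 h, and its neighbour ran from 151621353 to 151632301 (10949 bp), with 879, 1790 and 5301 bp at 24, 40 and 72 h. Another domain, on chromosome 5 from 92663160 to 92673882 (10723 bp), had 3914 bp at 72 h and 0 bp at 24 and 40 h. The densest bin of gained peaks, on chromosome 15 from 7100001 to 7200000, held 3 peaks in E2, 5 at 24 h, 5 at 40 h, 21 at 72 h and 22 at 120 h. The widest lost peak, on chromosome 8 from 123643077 to 123645106 (2030 bp), had 0 bp at 24 h and 657 bp at 72 h.

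Lost H3K27me3 peaks were found at 41.9% (37.4 to 46.5) at 24 h, 14.0% at 40 h and 21.7% (18.1 to 25.7) at 72 h, and gained peaks at 28.5%, 14.1% and 31.9%. Gained minus lost was -13.4 points (-18.2 to -8.83) at 24 h, 0.072 (-3.52 to 3.14) at 40 h and 10.2 (6.02 to 14.0) at 72 h. Gained exceeded lost on 2, 9 and 17 of 20 chromosomes. These values depended on the setting: at 24 h the difference was -4.42 when 50% of a peak had to be covered and -7.53 with peaks above the median width. At 40 h it was 6.58 (0.785 to 10.8) with those wider peaks but -8.45 (-12.5 to -4.44) with lists of equal length, and at 72 h 19.7 and 15.7, so no direction is read at 40 h. The 40 h list was the shortest of the mark and found 80.4% of common peaks, against 90.5% at 24 h and 89.4% at 72 h.

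The 2 marks of lysine 27 were then set against each other, since acetylation and trimethylation exclude each other on the same residue. H3K27ac peaks that were lost lay under an H3K27me3 peak in 0.690% of cases (0.538 to 0.871) in E2, 0.729% at 24 h, 0.769% at 40 h, 2.24% (1.96 to 2.54) at 72 h and 4.81% (4.40 to 5.24; 488 of 10148) at 120 h. The same peaks placed at random within their chromosomes gave 0.297% in E2 and 0.665% at 120 h. For common H3K27ac peaks the share was 0.124% in E2 and 0.451% (0.358 to 0.561) at 120 h, where random placement gave 0.714%. For gained peaks it was 0.263% and 0.591% (0.510 to 0.682), within the counting error of the random 0.654% at 120 h. In the other direction, gained H3K27me3 peaks lay on an H3K27ac peak in 6.75% of cases in E2, 4.82% at 24 h, 2.90% at 40 h, 1.05% at 72 h and 3.19% at 120 h, where random placement gave 1.21%, 1.52%, 1.18%, 0.999% and 2.01%. Lost H3K27me3 peaks lay on H3K27ac in 1.49% of cases in E2 and 6.17% (4.17 to 8.74) at 120 h.

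**Figure D4:**
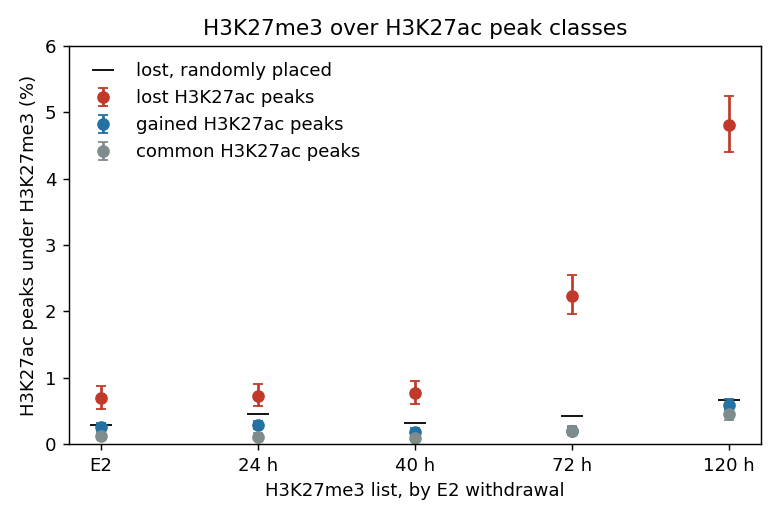
The percentage of H3K27ac peaks under an H3K27me3 peak (y axis) is plotted for lost, gained and common H3K27ac peaks at each condition (x axis), 1 library each, with 95% Clopper-Pearson intervals. Lost peaks stood at 0.690% in E2, 2.24% at 72 h and 4.81% at 120 h.

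The next comparison concerned the sites of the tagged proteins. The V5 list of V5-Hoxa9-AM cells lay near genes of mature and immature myeloid cells alike: a site within 10 kb was found for 10 of 12 primary granule genes (2.86 in lists of the same gene lengths), 25 of 34 neutrophil maturation genes (8.52), 21 of 30 monocyte and macrophage genes (9.36), 21 of 25 surface genes (8.37) and 21 of 30 myeloid transcription factor genes (8.36), each at percentile 100. Interferon and inflammation genes followed with 11 of 21 (5.64, percentile 99.3), stem and progenitor genes with 25 of 41 (16.1, percentile 99.8) and housekeeping genes with 11 of 20 (5.40, percentile 99.6). Developmental Polycomb target genes had 2 of 40 (10.6, percentile 0.01) and cell cycle genes 6 of 20 (6.10). Against genes carrying H3K4me3 only, the percentiles were 88.4 for stem and progenitor genes, 81.9 for interferon and inflammation genes and 84.2 for housekeeping genes. The other lists had 3 of 18 erythroid and megakaryocyte, 5 of 20 lymphoid, 7 of 18 mast cell, eosinophil, basophil and dendritic, 8 of 15 fibroblast and epithelial and 10 of 22 chromatin modifier genes, at percentiles of 19.98, 20.9, 88.0, 92.8 and 54.4. The shorter AM list of these cells differed for neutrophil maturation genes, with 8 of 34 (4.43, percentile 95.4). Against genes carrying H3K4me3 only, that percentile was 82.1. In the AM list stem and progenitor genes had 21 of 41 (9.47, percentile 100, and 98.4 against marked genes). Primary granule, monocyte and macrophage, surface and myeloid transcription factor genes also lay at percentile 100 there.

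The shorter V5 list of V5-ER-Hoxa9-AM cells in E2 had a site near 13 of 41 stem and progenitor genes, against 2.22 in lists of the same gene lengths (percentile 100), among them Cd34, Flt3, Meis1, Cdk6 and Muc13. It lay near 5 of 30 monocyte and macrophage genes (0.965, percentile 99.9), 3 of 12 primary granule genes (0.218, percentile 99.9) and 4 of 18 genes of mast cells, eosinophils, basophils and dendritic cells (0.439, percentile 99.96). The counts were 3 of 21 for interferon and inflammation genes (percentile 99.4), 3 of 25 for surface genes (97.6), 2 of 20 for lymphoid genes (89.5), 2 of 34 for neutrophil maturation genes (91.5), 2 of 30 for myeloid transcription factor genes (87.6) and 1 of 15 for fibroblast and epithelial genes (72.0). Cell cycle, erythroid and megakaryocyte, housekeeping, Polycomb target and chromatin modifier genes had 0. Against genes carrying H3K4me3 only, the mast cell, eosinophil, basophil and dendritic list had 0 of 4 (percentile 45.95) and the surface list 1 of 20 (64.2). On that background the percentiles were 99.99 for stem and progenitor, 99.94 for monocyte and macrophage, 99.92 for primary granule and 99.3 for interferon and inflammation genes. Sites near Cdk6 and Muc13 were picked as examples after their values were seen.

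The widest V5 site of V5-Hoxa9-AM cells lay in Nlrp3 (mm10 chromosome 11, 59540120 to 59542763, 2644 bp). The next lay in Cited2, which encodes a transcriptional co-regulator (chromosome 10, 17721620 to 17724059), in Ntn4, and 12078 bp from Pck1 and 21524 bp from Cxcr4, the chemokine receptor that holds progenitors in the marrow. Further sites lay inside Vav3, Galntl6 and Angpt1 and 9642 bp from Bcl2, an inhibitor of apoptosis, 16259 bp from Map3k7cl, 29920 bp from Lta4h and 109220 bp from Slco6c1, the nearest gene in each case. In all 3 V5 lists, 235 sites were shared. The widest of these were the Cxcr4 site (chromosome 1, 128613823 to 128615715), sites inside Scp2, Cdk6, a kinase of the G1 phase (chromosome 5, 3501617 to 3502973), Myh9, Kcnh7, Csmd1 and Tcf12, an E-protein gene, and sites with B3gnt5, Gpr84, Tmem8b, Stxbp5 and Ccser2 as the nearest gene, at 61266, 1867, 1229, 6161 and 557250 bp.

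Between the lists titled V5 and AM, 91.5% (90.8 to 92.1) of the AM peaks of V5-Hoxa9-AM cells were in the V5 list, and 36.4% of its V5 peaks were in the AM list. In V5-ER-Hoxa9-AM cells in E2, 98.8% of the AM peaks were in the V5 list. As both AM samples carry V5 as their antibody label, these shares may compare ChIPs with the same antibody. Agreement between different epitopes is not read from them. Of the 1417 V5 peaks of V5-ER-Hoxa9-AM cells in E2, 76.1% (73.8 to 78.4) were in the V5 list of V5-Hoxa9-AM cells, where random placement gave 0.581%, and 6.35% of the latter were in the former. After 72 h without E2 and 48 h of restored E2, 62.0% (57.0 to 66.9) of the 387 sites were in the E2 list of the same cells and 97.2% in the V5-Hoxa9-AM list. Of the 1417 E2 sites, 16.9% were found after restoration, a share limited by the length of the shorter list. Every shared site had identical coordinates in both lists, so the lists drew on a common set of intervals and the overlaps are those of chosen intervals, not of separate calls. With each list reduced to its 258 widest peaks, 28.3% of the V5-ER-Hoxa9-AM sites in E2 were in the V5-Hoxa9-AM list. At that length 44.6% of the V5-ER-Hoxa9-AM sites in E2 were found after restoration. A shared site had the same width in both lists, so this cut did not rank sites by their signal in each list.

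Sites of V5-Hoxa9-AM cells lay inside genes in 52.5% of cases and within 1 kb of a gene end in 10.8%. For V5-ER-Hoxa9-AM cells in E2 the shares were 47.7% and 3.32%. Gained H3K4me3 peaks lay on V5-Hoxa9-AM V5 sites in 13.1% of cases (12.4 to 13.8), common peaks in 8.95% (8.51 to 9.40) and lost peaks in 4.46% (3.41 to 5.72), all above random placement (0.512%, 0.658% and 0.481%). By genes the order differed: a V5-Hoxa9-AM V5 site lay within 10 kb of 45.85% of the 1278 gained genes against 48.8% in matched lists (percentile 1.15), 49.6% of genes marked in both against 48.9% (99.9) and 46.25% of lost genes against 45.2% (57.3). The AM list of the same cells gave 25.1% of gained genes against 28.0% (percentile 0.40). On V5-ER-Hoxa9-AM sites in E2 the shares of peaks were 1.17% of gained, 0.303% of common and 0.983% of lost peaks. Of the V5-Hoxa9-AM V5 sites, 8.32% (7.91 to 8.75) carried H3K4me3 in E2, 12.3% at 24 h, 12.5% at 40 h, 13.7% at 72 h and 16.9% (16.4 to 17.5) at 120 h. Of the V5-ER-Hoxa9-AM sites in E2, 3.74% carried it in E2, 7.34% at 24 h, 7.48% at 40 h and at 72 h, and 10.6% (9.03 to 12.3) at 120 h. The H3K4me3 and the V5 lists came from different cells, and the covered length of H3K4me3 was 10.4 Mb in E2 and 17.3 Mb at 120 h.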

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

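All tests of explanations in this part were chosen after the results were seen. A few H3K4me3 peaks lay on contigs that no comparison used, above the 3 peaks that a count of 0 allows. On JH584304 the E2 list had 15 peaks and the 24 h list 6, and on GL456211 the 24 h list had 5. At 120 h, GL456210 had 6 and GL456211, GL456212 and GL456221 had 5 each.

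The first pattern is that the share of gained minus lost H3K27ac peaks found after restoration was much higher at 72 h than at 24 or 40 h. The test took a less sensitive 72 h list to lower lost and common peaks by the same factor. From 40 to 72 h lost peaks were multiplied by 0.361, common peaks by 0.899 and gained peaks by 1.51, a ratio of 0.402 for lost over common. Lost peaks were narrower than common ones (median 237 against 360 bp), so lower sensitivity could remove them more often. The ratio therefore cannot exclude it, although lower sensitivity alone would not raise gained peaks. The step was 34.8 points with peaks within 1 kb merged and 30.9 with peaks above the median width, which argues against split regions and against weak, narrow peaks as its whole cause. What stays open is a difference between these single libraries, in sensitivity or otherwise, and the sign of the 72 h value itself, which was -1.23 among peaks above the median width. A loss of H3K27ac peaks of the E2 state between 40 and 72 h that 48 h of restored E2 did not undo may be the biological reading, as an untested hypothesis, but time back in E2 (80 h against 48 h) differed too and was not separated.

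The second pattern is that gained peaks outnumbered lost peaks in all 3 marks, by 7.42, 3.15 and 8.35 times for H3K4me3, H3K27ac and H3K27me3, but by 2.14, 1.11 and 1.95 times with lists of equal length, where 12713 H3K27ac peaks were lost and 14058 gained. A more sensitive 120 h library needs wider peaks at common places, and with the full lists these covered at least 1.24 times the length in E2 in each mark, so it could account for part of the excess. With 50% of a peak covered the ratios were 1.05, 0.953 and 1.06, but that setting counts a 120 h peak less than 50% covered as gained and so leaves out the peaks that widened most. As the whole of the H3K4me3 gains at neutrophil maturation genes it is argued against by their percentile of 100 among lists matched on covered length. An E2 library that called too little would also add gained peaks and genes. For H3K4me3 the E2 list was the shortest, with 17497 peaks. Of its peaks 94.6% were found at 24 h, but 69.9% of the 24 h peaks were found in E2. At 24 h, with E2 restored, 51.1% of the 1278 gained genes were marked. How much of the remaining excess is biological was not separable with 1 library per condition.

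The third pattern is the higher share of lost H3K27ac peaks under H3K27me3 at 120 h. More H3K27me3 called at 120 h would raise peaks placed at random alike, but the 6.97-fold rise at lost peaks was 3.11 times that at random placement; common peaks rose 3.64-fold, 1.70 times random, so part of the rise was not particular to lost peaks. Lost peaks rose 1.92 times as much as common ones (1.11 to 3.21 over chromosomes). Common peaks overlap an H3K27ac peak at 120 h by definition, and only 22 of 17728 lay under H3K27me3 in E2. This ratio therefore cannot decide whether the rise was general on H3K27ac places. Touching edges are argued against by the share with 50% of the peak covered, still 7.51 times higher at 120 h. Unequal sensitivity of the H3K27me3 libraries at particular kinds of chromatin stays open. No biological explanation was tested, and only 4.81% of the lost peaks were involved.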

How the results depend on the processing

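Alternatives by peak width, the window of the whole gene and 1 kb around it, and the background of H3K4me3-marked genes were chosen after seeing the data. Over 51 results and 172 alternative values, 96 stayed within their limits, 72 moved and 4 reversed. The limits were a factor of 1.5 for counts, the 95% interval of the first setting for shares and differences, and the same side of the outer 2.5% at either end for percentiles. Of the 96, 6 could not move, as V5 and AM lists share identical coordinates and 50% coverage changes nothing there. For those that moved the cause was not tested, except that both width settings hold fewer peaks by construction. Alternatives by score and motifs were not run. Read depth is unknown, and the 56 h H3K27ac list, with 6356 peaks, is the most limited. No paired analysis was possible because each group had 1 library.

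Requiring 50% of a peak to be covered gave 2033 H3K4me3 peaks lost. Gained minus lost H3K27ac was -34.9, -25.2, -1.22 and 1.69 points at 24, 40, 56 and 72 h, and H3K27me3 -4.42 at 24 h. Lost H3K27ac under H3K27me3 at 120 h was 3.89%. V5-Hoxa9-AM V5 sites on H3K4me3 were 3.80% in E2 and 10.5% at 120 h.

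Merging peaks within 1 kb gave 419 H3K4me3 peaks lost and 4510 gained, and 5438 H3K27ac peaks lost and 11204 gained. Gained minus lost H3K4me3 was -32.9 and -30.2 at 24 and 40 h and reversed to 5.26 at 72 h. For H3K27ac it was -32.2, -24.8, -1.23 and 10.05 at 24, 40, 56 and 72 h, and lost H3K27ac under H3K27me3 was 5.26%.

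Keeping only peaks above the median width of each list gave 4537 H3K4me3 peaks gained, 5663 H3K27ac lost and 16288 gained, and 173 H3K27me3 lost and 1731 gained. Gained minus lost H3K4me3 was -33.4 at 24 h. For H3K27ac it was -39.8 and -32.1 at 24 and 40 h, and reversed to 1.56 at 56 h and -1.23 at 72 h. For H3K27me3 it was -7.53, 6.58 and 19.7 at 24, 40 and 72 h. Lost H3K27ac under H3K27me3 was 3.64%. V5-Hoxa9-AM AM peaks in V5 were 99.0% and the reverse 39.4%; V5-ER-Hoxa9-AM E2 sites in V5-Hoxa9-AM were 96.7% and the reverse 8.06%; the 72 h sites in E2 were 73.1% and the reverse 19.9%. V5-Hoxa9-AM V5 sites on H3K4me3 were 5.42% in E2 and 10.5% at 120 h. Genes gaining H3K4me3 numbered 2425 and losing 279. Percentiles were 97.2 for monocyte and macrophage gains, 76.2 for primary granule gains, 7.25 for stem and progenitor gains and 90.4 for their losses.

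Lists of equal length gave 2210 H3K4me3 peaks lost and 4728 gained, 14058 H3K27ac gained, and 763 H3K27me3 lost and 1488 gained. Gained minus lost H3K4me3 was -27.9 and -34.6 at 24 and 40 h. For H3K27ac it was -34.2 and -33.8 at 24 and 40 h, reversed to 1.21 at 56 h, and 0.54 at 72 h. For H3K27me3 it was -8.45 at 40 h and 15.7 at 72 h. Lost H3K27ac under H3K27me3 was 3.18%. Of V5-Hoxa9-AM AM peaks 99.2% were in V5, as were V5 in AM (99.2%); 28.3% of V5-ER-Hoxa9-AM E2 sites were in V5-Hoxa9-AM and the reverse (28.3%), and 44.6% of 72 h sites in E2 and the reverse (44.6%), shares equal by construction. V5-Hoxa9-AM V5 sites on H3K4me3 were 12.4% in E2 and 18.2% at 120 h, and genes losing H3K4me3 numbered 151.

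With any peak in the gene or 1 kb around it, 1406 genes gained H3K4me3 and 92 lost it. A window of 2.5 kb put stem and progenitor gains at percentile 5.41. Against H3K4me3-marked genes, stem and progenitor genes near V5-Hoxa9-AM V5 sites lay at percentile 88.4. Neutrophil maturation, surface and interferon gains stayed within their limits in every setting run.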

Other observations

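The gene families, the covered lengths and the test in this part were chosen after the values were seen. Replication-dependent histone genes, which are transcribed in S phase, carried H3K4me3 at a gene end in 51 of 62 cases in E2, 58 at 24 h, 60 at 40 h, 60 at 72 h and 62 at 120 h, with 11 gained and 0 lost. Over all genes the number marked was also lowest in E2: 9045, against 9689, 9671, 9908 and 10243 at 24, 40, 72 and 120 h. Of the 10323 genes marked in E2 or at 120 h, 1278 gained and 80 lost the mark. Of 8 Gimap genes, which encode GTPases of lymphocytes, 4 were marked in E2, at 24 h and at 40 h, 3 at 72 h and 1 at 120 h, with 0 gained and 3 lost. No matched lists were drawn for either family. The covered length of H3K4me3 was 10.4, 14.2, 14.9, 16.04 and 17.3 Mb in E2 and at 24, 40, 72 and 120 h. H3K27me3 covered 12.9 Mb at 120 h and 5.47 Mb in E2, and H3K27ac covered 21.5 Mb at 120 h, 10.7 Mb in E2 and 1.999 Mb at 56 h.

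One hypothesis was examined through a percentile, which ranks single libraries and gives no p-value: that ER-HOXA9 sites in E2 lie near the genes that lost H3K4me3 at 120 h. Of the 80 lost genes of the full lists (151 with lists of equal length, not tested here), 9 (11.25%, 5.28 to 20.3) had a V5-ER-Hoxa9-AM site of the E2 list within 10 kb, against 3.80% in matched lists of H3K4me3-marked genes, at percentile 99.95 of 1000 lists. The genes were Gpr12, Gimap6, Stard10, Ccr2, Tespa1, Igll1, Muc13, Srf and Dntt, with 11 distinct sites. This may point to direct upkeep of these genes by ER-HOXA9, but 15 such percentiles were computed, the gained genes also lay high with the same list (84 of 1278, 6.57% against 5.25%, percentile 98.5), and the longer V5-Hoxa9-AM V5 list gave 57.3 for the lost genes and 1.15 for the gained genes (45.85% against 48.8%). The lists thus differed for the gained genes, no direction is read, and the sites came from other cells than the H3K4me3 lists.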
